A study of Arabidopsis thaliana with 58 samples.

How the data were processed

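The series holds 58 samples of whole Arabidopsis seedlings, 9 days old. Compared here were 30 ChIP-seq peak lists, 1 per library. They comprise 18 lists for H3K4me1, H3K4me2 and H3K4me3 in WT and in pkl, a mutant in the chromatin remodeler gene PICKLE (PKL), and 12 lists from an anti-PKL ChIP in WT, jaw-5D, pifQ and hy5. Each of these groups has 3 libraries, described as biological replicates, so p-values measure spread between samples. RNA-seq of pkl (3 libraries) was used for expression levels. The 10 Hi-C samples and the 15 input samples were not analysed here. The RNA tables also hold 6 columns that match no sample label (3 per table). They were left out, and no expression comparison between genotypes was made.

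The authors' processing notes name fastp, HISAT2 2.1.0, SAMtools 1.6, Bowtie2 2.3.3, MACS2 2.2.5, deepTools and the TAIR10 genome, without the role of each tool. The RNA count table of the authors gives raw counts per gene, with the exon length of the gene in bp. The deposited FPKM are scaled by that length in kb and by a library total larger than the summed gene counts. In the deposited peak lists, the score is 10 x -log10 q shortened to a whole number. The ratio given by the authors for each peak is the fold enrichment at the peak summit over the local background. The deposited lists further give -log10 p and -log10 q (neg_log10_p) for each peak, and the summit offset from the peak start in bp. Score and fold enrichment are the authors' values and were not recomputed. The control library behind them is not stated. The lists hold no read totals, so the depth of the ChIP libraries is unknown, and the number of peaks and the genome covered are given instead. Total counts of the RNA libraries ran from 17300314 to 17656899. The PKL lists of WT end at q = 0.01 and name chromosomes in another way than all other lists, which end at q = 0.05. In the PKL comparisons with WT the format of the list therefore coincides with the genotype.

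Gene positions (TAIR10) came from the count table, with 33610 genes, of which 279 chloroplast and mitochondrial genes were left out and 33331 nuclear genes were kept. Symbols and gene types came from a RefSeq table that matched 28932 of the identifiers, and RefSeq symbols are used. For each gene and library, the bp under peaks were summed. For histone marks the window was the gene, with at least 150 bp counting as marked, and for PKL the gene with 1000 bp upstream and at least 50 bp. Genes marked in at least 3 libraries were tested with limma 3.58.1 (lmFit and eBayes) on log2 of bp plus 100, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. "Longer" and "shorter" mean more and fewer bp under peaks in the first-named group. These values describe the length called as enriched, not the amount of signal. The 12 PKL libraries were fitted together. Where a gene was listed at 0 bp in every library of a group, the fitted log2 value depends on the added 100 bp and is no bound, so mean bp with SD is given instead. In such genes 1 group has no spread, while limma uses 1 pooled spread for both groups. Where only some libraries of a group were at 0 bp, log2 values depend on the added bp in part.

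Centring subtracted each library's median over the genes marked in every library of that antibody. For PKL these are at most the 264 genes bound in all 3 WT libraries. Centring moved the group difference by -0.16 (log2) in H3K4me2 and by 0.11 in hy5 against pifQ. Against WT it moved by -1.15, -1.23 and -1.11 in jaw-5D, pifQ and hy5. In these 5 comparisons log2 values, adjusted p-values and calls of genes are given relative to that shift ("centred"), unless stated. Counts over other splits of the libraries, overlaps between marks and with bound genes, list tests, gene types, expression of called genes and distances between genes use calls without centring in all comparisons. In the others the shift was at most 0.08 in size, and values are given without centring. After centring, the median log2 value over all genes tested was still 0.819, 0.732 and 0.597 in jaw-5D, pifQ and hy5 against WT.

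Peaks per library were compared by exact two-sided permutation tests over all splits of 3 against 3, which cannot go below p = 0.1. Genes marked in all 3 libraries of 1 group and in 0 of the other were counted. Overlap of PKL peaks in WT with changed genes was tested by Fisher's exact test, two-sided and adjusted over 6 tests. Correlations across genes are Spearman's, and genes are not independent replicates. A total of 14 gene lists was fixed: seed and embryo genes (19 members), elongation genes linked to PIF factors (18), light and HY5-linked genes (21), TCP-linked and leaf genes (22), PIF factors (4), H3K4 methyltransferases (11), H3K4 demethylases (11), chromatin remodelers (6), PRC2 (7), floral genes (16), gibberellin genes (10), clock genes (10), root genes as markers of another organ (8) and housekeeping genes (9). They were tested with camera (correlation preset at 0.01, and estimated) and with fry. Lists with fewer than 4 tested members have counts only. Camera compares a list with the other genes, so its direction can differ from the sign of the list's median or mean. Of 81 list tests 4 passed with camera, 0 with an estimated correlation and 28 with fry, which does not compare a list with other genes. In the 4 lists that passed, median, mean and test had the same sign.

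Named genes are the protein-coding genes with a symbol that passed the test and whose groups did not overlap: the 10 largest positive and the 10 largest negative changes, ranked on values without centring. To these were added list members that passed, PKL itself, the 10 genes bound by PKL in WT with the highest mean score percentile, and the 10 longest genes marked in 1 group and not in the other. Groups, comparisons, gene lists, this rule and most alternatives were fixed before the data were examined. Chosen after the values were seen were the comparisons between mutants, the matched q threshold of 0.01 and its combination with centring, centred calls in the overlap with bound genes, and centred counts with 1 library left out. Where 1 library was left out, the genes of the full test were kept. That choice was made after a first run that filtered again had, by construction, removed genes covered in the reduced group alone. Alternatives tried were median centring, 50 or 500 bp added in place of 100, no filter, peaks with -log10 q of at least 10, equal numbers of peaks, other windows, a replicate block, non-overlap of the groups, an overlap of 1 or 500 bp, merged regions, each library left out, other definitions of bound genes, logistic regression with gene length, and CPM.

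The test was tested on simulated data with 200 changed genes. Simulated noise was normal with the same spread in both groups, and no group was held at 0 bp. The rates below therefore do not describe genes at 0 bp in every library of 1 group, as most called genes were. Changes of 0.5, 1 and 2 (log2) were recovered in 14.0%, 63.0% and 81.5% of these genes for H3K4me1, in 0%, 31.5% and 74.5% for H3K4me2, and in 69.5%, 89.0% and 94.0% for H3K4me3. For PKL against WT, changes of 0.5 and 1 were recovered in 0% of genes in each comparison. A change of 2 was recovered in 47.5% for jaw-5D, 47.0% for pifQ and 39.0% for hy5, with 5, 8 and 7 false calls. For changes of 0.5, 1 and 2, false calls numbered 3, 5 and 11 in H3K4me1, 0, 2 and 10 in H3K4me2, and 7, 5 and 6 in H3K4me3. The comparisons between mutants were not simulated. Work was done in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9) and R 4.3.3.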

Results

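Histone H3K4 methylation and PKL binding were mapped in whole seedlings grown for 9 days. PKL is a CHD3-type chromatin remodeler. H3K4me1, H3K4me2 and H3K4me3 were profiled in WT and in pkl, with 3 libraries per mark and genotype. PKL was profiled in WT and in 3 lines with altered transcription factors, with 3 libraries each: jaw-5D, in which TCP transcripts are lowered by a microRNA, pifQ, which lacks PIF1, PIF3, PIF4 and PIF5, and hy5, which lacks the light-signalling factor HY5. RNA of pkl was sequenced in 3 libraries with total counts of 17584037, 17300314 and 17656899. Peaks per library in replicates 1, 2 and 3 numbered 15263, 14982 and 14976 for H3K4me1 in WT, and 14395, 14727 and 15441 in pkl. For H3K4me2 there were 20594, 20310 and 19880 peaks in WT, and 20483, 21880 and 21431 in pkl. For H3K4me3 there were 16413, 16514 and 16639 in WT, and 16795, 16899 and 16545 in pkl. PKL lists held 821, 632 and 2824 peaks in WT, 13136, 12437 and 12619 in jaw-5D, 12792, 12443 and 13979 in pifQ, and 11542, 11379 and 12181 in hy5. Read depth of the ChIP libraries is unknown.

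**Figure D1:**
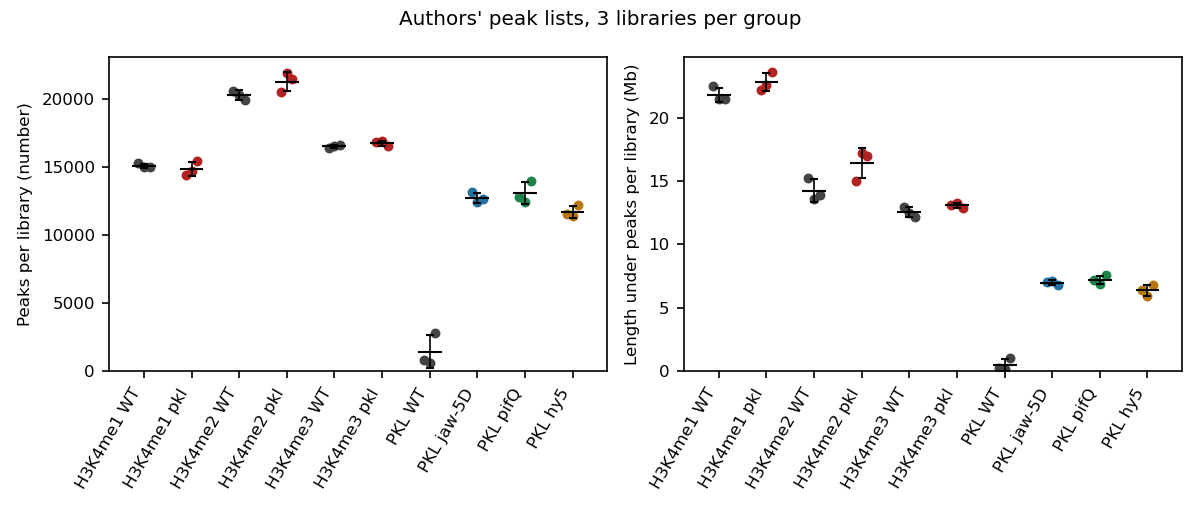
Number of peaks (left) and Mb of the genome under peaks (right) for each of the 30 ChIP libraries, by group. Points are libraries and bars are mean ± SD (n = 3). The PKL lists of WT hold 632 to 2824 peaks and those of the mutants 11379 to 13979.

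The comparison of pkl with WT asked where H3K4 methylation depends on PKL. A gene at 0 bp is one where no peak was called, so gains and losses below are those of called peaks. The amount of signal was not compared. In H3K4me1, VSR6, a vacuolar sorting receptor (chromosome 1, 10997275 to 11000543), was listed at 0 bp under peaks in all 3 WT libraries and had 1139.7 ± 358.3 bp in pkl (mean ± SD, n = 3, limma adjusted p = 0.00456). FRO3, a ferric reductase (chromosome 1, 8150070 to 8153530), went from 0 to 981 ± 172 bp (adjusted p = 0.00132). CuAO1, a copper amine oxidase, rose from 0 to 744 ± 133 bp, the transcription factor gene MYB67 to 678 ± 171 bp, and DFO, needed for meiotic DNA breaks, to 592 ± 73.0 bp. Longer peaks from 0 bp in WT were also found at UBC5, a ubiquitin-conjugating enzyme (558 ± 98.7 bp), SYTB, a synaptotagmin (555 ± 240.5 bp), and the MADS-box gene AGL99 (543 ± 242 bp). CYP705A4, a cytochrome P450, had 481 ± 78.6 bp in pkl, and NFU5, an iron-sulfur cluster protein, had 467 ± 104 bp. Adjusted p-values of these 8 genes ran from 0.00121 to 0.0341.

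In the other direction, RPL, a homeodomain factor of fruit and stem patterning (chromosome 5, 395634 to 399041), lost its H3K4me1 peak, from 433 ± 70.9 bp in WT to 0 in pkl (adjusted p = 0.0014). Peaks of 396 ± 54.5 bp at THX, a plastid thioredoxin, and 375 ± 107 bp at FBA1, a plastid aldolase, were also absent in pkl. So were 355 ± 51.6 bp at PAL4, a phenylalanine ammonia-lyase, and 357 ± 69.3 bp at HOG1, a S-adenosylhomocysteine hydrolase. PEX4 (325 ± 53.1 bp in WT), PFN2, a profilin (312 ± 56.5 bp), and CPK24, a calcium-dependent kinase (275 ± 45.6 bp), were listed at 0 bp in pkl as well. The RNA helicase gene MEE29 (chromosome 2, 14872320 to 14879739) kept part of its H3K4me1 peak cover, 1175 ± 300 bp in pkl against 5000.3 ± 173.9 bp in WT (log2 -2.03, adjusted p = 0.0138). All 3 pkl values lay on the same side of all 3 WT values in each gene named so far, as the rule for naming genes requires. PEX4 was the one member of the 14 gene lists that passed for H3K4me1. It is 1 of 8 housekeeping genes tested, and 1 was shorter adjusted over the list alone. The housekeeping list lay below other genes (camera adjusted p = 0.0225), with adjusted p = 0.545 with an estimated correlation. Its median log2 value was -0.0312 and its mean -0.276, so the call rests largely on PEX4. The list without PEX4 was not tested. In the remaining lists 0 members passed, over all genes or adjusted over the list alone.

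Of 13469 genes tested for H3K4me1, 74 were longer and 20 shorter in pkl, and 1007 had an unadjusted p under 0.05. Another split of the same libraries called 54 genes, against 94 for the real one. Adjusted p-values of the genes named for this mark can therefore understate the share of false calls. Of the longer genes 63 were at 0 bp in every WT library, and of the shorter ones 18 were at 0 in every pkl library. Groups did not overlap in 1519 genes with higher and 377 with lower pkl values, 14.1% of those tested, where chance gives 10%. Genes with a peak in all 3 libraries of pkl and 0 of WT numbered 73, against 19 the other way, 92 in all. Another split of the same libraries reached 68 such genes, so most of this count can arise without a difference in genotype. Among the 73 genes, 3xHMG-box2 (897 ± 647 bp) and SNAP29 (581 ± 152 bp) stood with the longest. Without pkl replicate 3 there were 64 longer and 49 shorter genes, and with peaks of -log10 q of at least 10 there were 328 and 4. A replicate block left 0 longer and 0 shorter genes. Peaks per library averaged 14854 ± 534 in pkl and 15074 ± 164 in WT (exact permutation p = 0.5, n = 3), a difference of -219, which was 10.3 without pkl replicate 1 and 1899 with the stricter peaks (exact permutation p = 0.1). They covered 22.8 ± 0.724 and 21.8 ± 0.565 Mb (exact permutation p = 0.2).

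In H3K4me2, SPL2, a phase-change transcription factor (chromosome 5, 17360287 to 17363773), had 1139.7 ± 289.6 bp in pkl and 0 in WT (n = 3, limma adjusted p = 0.000921, centred). RBL15, a rhomboid-like protein, gained 941 ± 231 bp and RR2, a cytokinin response regulator, 865 ± 378 bp. Peaks present in pkl and absent in WT also covered 714 ± 124 bp of SSI2, a stearoyl-ACP desaturase, 728 ± 258 bp of the cold-regulated gene COR413-PM2, 715 ± 223 bp of the GRAS gene SCL1 and 727 ± 322 bp of the bZIP gene BZO2H3. ELF8, a subunit of the Paf1 complex, had 681 ± 149 bp, GRF7, a 14-3-3 protein, 643 ± 220.5 bp, and SRS5, of the SHI family, 604 ± 158 bp. Centred adjusted p-values of these 9 genes ran from 0.000512 to 0.0170.

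No H3K4me2 peak was called in pkl at JAG, a zinc-finger factor of lateral organs (chromosome 1, 25684314 to 25686165, 389 ± 25.1 bp in WT, centred adjusted p = 0.000414). Peaks called in WT were also absent in pkl at CYP87A2 (532 ± 138 bp in WT), PD1, an arogenate dehydratase (532 ± 182 bp), CYP71B22 (473 ± 163 bp), the acyltransferase gene BAT1 (432 ± 157 bp) and ROC3, a cyclophilin (412 ± 109 bp). GLIP2, a lipase (383 ± 45.8 bp), COPT3, a copper transporter (382 ± 30.4 bp), and ALF5, a MATE transporter (394 ± 146 bp), were at 0 bp in pkl too. Among 8 floral genes tested, 2 were shorter: the MADS-box gene SHP2 fell from 388 ± 29.7 bp and WUS, which maintains shoot stem cells, from 378 ± 25.6 bp, both to 0. Adjusted over the list alone, without centring, 1 floral gene was longer and 3 were shorter. The floral list lay below other genes (camera adjusted p = 0.00194), with adjusted p = 0.237 with an estimated correlation. Without centring its median log2 value was -0.145 and its mean -0.351, which SHP2 and WUS pull down. The list without SHP2 and WUS was not tested.

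CHR5, a CHD-family remodeler (chromosome 2, 5544181 to 5556464), rose from 578 ± 105 to 2130.3 ± 569.7 bp of H3K4me2 (centred log2 1.54, adjusted p = 0.0269, n = 3). It is 1 of 6 remodelers tested. CHR4, another CHD-family remodeler, passed as well with centring (adjusted p = 0.0497) and not without, and 2 were longer adjusted over the list alone. The remodeler list did not pass against other genes (camera adjusted p = 0.0764, 0.741 with an estimated correlation). LDL3, a LSD1-like demethylase, rose from 132 ± 56.6 to 775 ± 134 bp (centred log2 1.77, adjusted p = 0.00856). It was the one of 10 H3K4 demethylases to pass, and 3 were longer adjusted over the list alone (LDL3, PKDM7D and JMJ18), while the demethylase list did not pass (camera adjusted p = 0.270, 0.741 with an estimated correlation). PHE1, a MADS-box gene of the endosperm, went from 0 to 528 ± 125 bp as 1 of 8 seed and embryo genes, with 1 longer adjusted over the list alone. None of 7 PRC2 genes passed by limma, 3 were longer adjusted over the list alone, and the list lay above other genes (camera adjusted p = 0.0414), with adjusted p = 0.682 with an estimated correlation. For clock genes 0 of 10 passed and 1, ELF3, was longer adjusted over the list alone. In the elongation, gibberellin, methyltransferase, housekeeping, light, PIF, root and TCP lists 0 members passed either way.

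Of 19001 genes tested for H3K4me2, 178 were longer and 121 shorter after centring by -0.16, and 222 and 109 before it. With peaks of -log10 q of at least 10 there were 456 and 30. Before centring 2752 genes had an unadjusted p under 0.05, 135 of the longer genes were at 0 bp in WT and 97 of the shorter ones at 0 in pkl. Without pkl replicate 2 the counts turned to 145 longer and 193 shorter with centring, and 156 and 178 without. Groups did not overlap in 3591 and 726 genes, 22.7% against a chance share of 10%. Genes marked in all 3 libraries of 1 genotype and 0 of the other numbered 148 in pkl and 99 in WT (125 and 134 with equal numbers of peaks), and TMN1 (920 ± 679 bp), UBP2 (736 ± 501 bp) and the methyltransferase gene SDG25 (684 ± 362 bp) were among the longest of pkl. Peaks per library averaged 21265 ± 713 in pkl and 20261 ± 359 in WT, and covered 16.4 ± 1.19 and 14.2 ± 0.888 Mb (exact permutation p = 0.2 for each, n = 3).

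In H3K4me3, SQE6, a squalene epoxidase (chromosome 5, 8183075 to 8186640), had 1076.7 ± 26.7 bp in pkl and 0 in WT (n = 3, limma adjusted p = 7.07e-07). GT13 gained 692 ± 58.2 bp, CYP71B36 682 ± 31.2 bp and DTX1, a MATE transporter, 642 ± 66.6 bp. Peaks absent in WT covered 498 ± 19.0 bp of LSH7 and 451 ± 13.8 bp of HTA11, a H2A.Z histone (adjusted p = 1.57e-06 for both). MES18, a methyl esterase, had 485 ± 142 bp, ASE3, of purine synthesis, 451 ± 190.1 bp, the amino acid transporter gene LHT2 421 ± 71.7 bp, and INP1, of pollen apertures, 430 ± 136 bp. SPCH, which starts the stomatal lineage (chromosome 5, 21586606 to 21588941), lost its H3K4me3 peak, from 631 ± 109 bp in WT to 0 in pkl (adjusted p = 9.68e-05). LOL1 (628 ± 111 bp in WT), the dark-inducible gene SEN1 (557 ± 276 bp) and DML1, a DNA glycosylase that removes DNA methylation (481 ± 162 bp), were at 0 bp in pkl. The same was found for AHP1, a cytokinin phosphotransfer protein (407 ± 134 bp), DIN9 (385 ± 45.0 bp), MEE29 (391 ± 125 bp) and RLK1, a receptor kinase (341 ± 43.6 bp). Transporter genes AMT1;4 for ammonium (360 ± 56.1 bp) and NRT1.7 for nitrate (356 ± 112 bp) lost their peaks too.

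Among 10 elongation genes tested, EXPA8, an expansin that loosens cell walls (chromosome 2, 16948863 to 16950557), fell from 1020 ± 111 to 340 ± 7.2 bp of H3K4me3 (log2 -1.34, adjusted p = 0.000585). There was 1 shorter elongation gene adjusted over the list alone. The elongation list lay below other genes (camera adjusted p = 0.00258), with adjusted p = 0.579 with an estimated correlation. Of 3 floral genes tested, MAF4, a relative of the flowering repressor FLC, gained 374 ± 38.7 bp from 0 (adjusted p = 2.81e-05), and 1 was longer adjusted over the list alone. None of 18 light genes passed by limma, while 1 was longer (TT4) and 1 shorter (GUN5) adjusted over the list alone. GUN5 also passed with centring (adjusted p = 0.0284). In the other 11 lists 0 members passed either way for H3K4me3.

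Of 16637 genes tested for H3K4me3, 186 were longer and 65 shorter in pkl, and 2146 had an unadjusted p under 0.05. Of these, 105 longer genes were at 0 bp in WT and 55 shorter ones at 0 in pkl. Groups did not overlap in 2718 and 611 genes, 20.01% against a chance share of 10%. Peaks present in all 3 libraries of 1 genotype and 0 of the other were found at 111 genes in pkl and at 57 in WT, PDLP8 (341 ± 66.3 bp) among the latter. Peaks per library averaged 16746 ± 182 in pkl and 16522 ± 113 in WT, and covered 13.1 ± 0.197 and 12.5 ± 0.387 Mb (exact permutation p = 0.2 for each, n = 3). At PKL itself (chromosome 2, 10713807 to 10723986) no mark passed. H3K4me1 covered 9065 ± 58.8 bp in pkl and 8769 ± 114 in WT, H3K4me2 761 ± 748 and 101 ± 174 bp, and H3K4me3 632 ± 31.0 and 586 ± 43.6 bp.

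**Figure D2:**
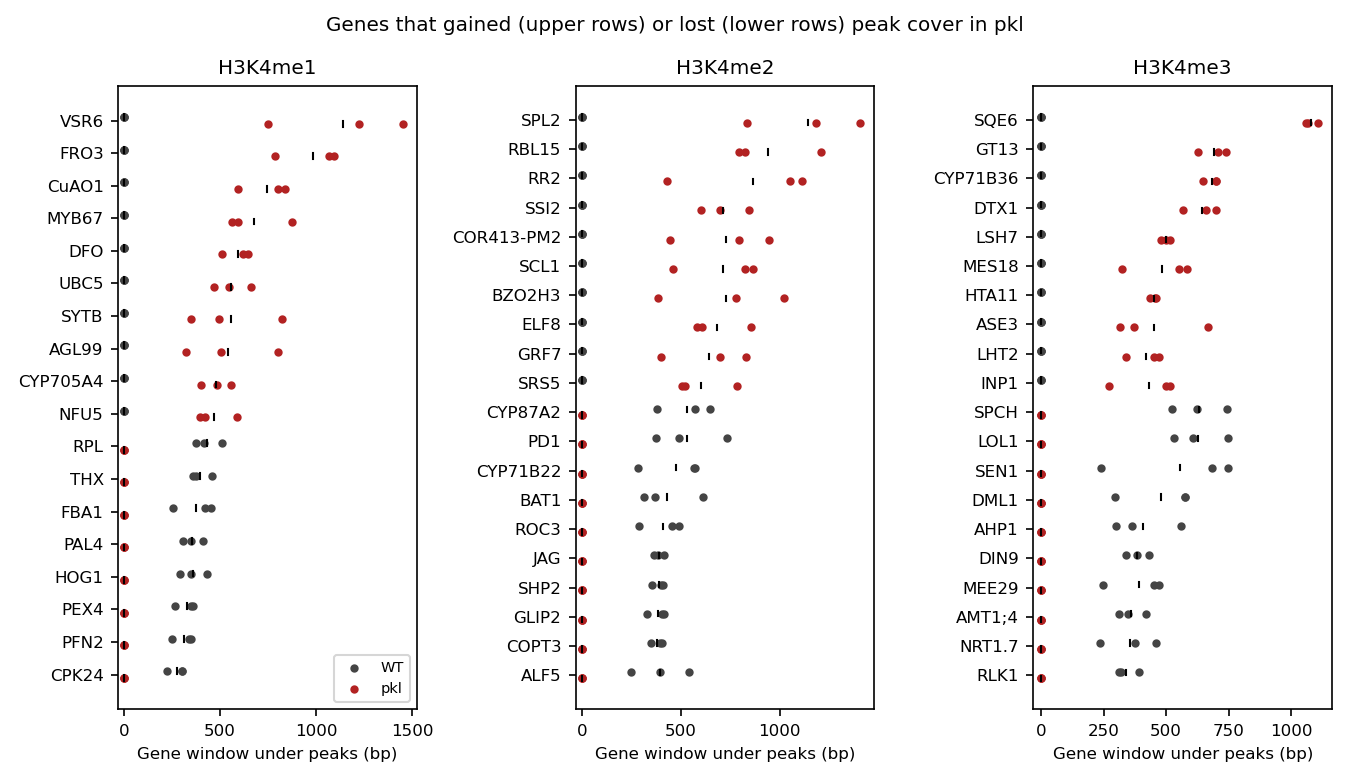
H3K4me1, H3K4me2 and H3K4me3 peaks over named genes, in bp under peaks per gene, for the 3 WT and 3 pkl libraries (points) with the mean (tick). SQE6 has 1076.7 bp of H3K4me3 in pkl and 0 in WT, while SPCH has 631 bp in WT and 0 in pkl. MEE29 is left out of the H3K4me1 panel because of its length.

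A few genes changed the same way in more than 1 mark, while a correlation across all genes was not shown beyond other splits of the libraries. Spearman's correlation of the log2 changes, across genes that are not independent replicates, was 0.0579 between H3K4me1 and H3K4me2. It was 0.101 between H3K4me1 and H3K4me3, and 0.0824 between H3K4me2 and H3K4me3. Of the 81 pairs of other splits of the libraries, 18, 6 and 12 gave values as large in size. In calls without centring, CYP705A4 was longer in H3K4me1 and H3K4me2, and SDR2, a short-chain reductase, and GMI1, a DNA repair gene, were longer in H3K4me1 and H3K4me3. SERK1, a receptor kinase, was longer in H3K4me2 and H3K4me3, and MEE29 was shorter in H3K4me1 and H3K4me3. Genes longer in both marks numbered 1, 4 and 8 for the 3 pairs of marks, where independence gives 0.548, 0.252 and 1.32. Those shorter in both numbered 2, 2 and 3, where independence gives 0.0135, 0.0241 and 0.0941, and 0 genes changed in opposite directions. These overlaps were not counted over other splits of the libraries. AT5G43800.1 (chromosome 5, 17597379 to 17605019) was shorter in all 3 marks and was listed at 0 FPKM in pkl. It falls outside the rule for named genes and was chosen after its values were seen.

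In WT, the anti-PKL ChIP asked where PKL sits on the genome. The 10 genes bound in all 3 lists with the highest mean score percentile included the corepressor genes TPL (chromosome 1, 5414817 to 5421033, 711 ± 79.2 bp, n = 3), TPR1 (555 ± 108 bp) and TPR3 (432 ± 40.7 bp). They also included WRKY22 (75.7 ± 15.1 bp), WRKY47 (452 ± 49.4 bp), AT5G61997, AT5G01850 and AT4G38840, which shares its peak with SAUR15 (488 ± 43.0 bp). The highest percentiles were those of AT2G48160 (241 ± 20.8 bp) and AT3G33072.1 (392 ± 30.04 bp), bound in 5 and 0 of the 9 mutant libraries, while the others named were bound in all 9. Among 10 clock genes, 5 had a PKL peak in at least 2 of 3 WT libraries: PRR5, PRR7, PRR9, PCL1 (LUX) and GI. Of 18 elongation genes 6 did, PRE1, IAA19, SAUR15, SAUR63, HFR1 and CKX5, and of 21 light genes 4 did, RBCS1A, CAB1, CAB3 and ELIP1. PIF4 and PIL6, known as PIF5 (2 of 4 PIF factors), SHY2 and AN3 (2 of 22 TCP-linked genes), ACT7 and UBQ10 (2 of 9 housekeeping genes), AP1, GAI and WRI1 were bound too. The H3K4 methyltransferase, demethylase, remodeler, PRC2 and root lists had 0 bound members. PKL itself had 0 bp of PKL peak in all 12 libraries.

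PKL peaks in WT covered 264 genes in all 3 libraries, 718 in at least 2 and 2395 in at least 1. Of the 718 genes, 34.3% had H3K4me1 in all 3 WT libraries, 69.2% had H3K4me2 and 79.7% had H3K4me3, against 36.2%, 51.3% and 48.2% of all genes. Genes bound by PKL in WT were compared with genes changed in pkl, called without centring. H3K4me2 became longer at 6 bound genes of 222 (odds ratio 0.935, 95% interval 0.338 to 2.08) and shorter at 5 of 109 (odds ratio 1.62), which was 0.917 when bound meant at least 1 WT library. H3K4me3 became longer at 5 of 186 (odds ratio 0.765, 95% interval 0.245 to 1.83) and shorter at 2 of 65 (odds ratio 0.882). H3K4me1 became longer at 0 of 74 (upper limit of the odds ratio 2.44) and shorter at 0 of 20. With centred calls, added after the values were seen, the odds ratios were 1.18 for longer (6 of 178) and 1.46 for shorter H3K4me2 (5 of 121), and 0.830 for longer and 1.16 for shorter H3K4me3. Fisher's exact test gave an adjusted p of 1 in all 6 tests, without and with centring.

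The comparison of PKL in the mutants with WT asked whether PKL binding needs TCP, PIF and HY5 factors. The mutant lists had PKL peaks over more genes than the WT lists. In jaw-5D, ADC2, an arginine decarboxylase (chromosome 4, 16560062 to 16562969), had 3614 ± 122 bp of PKL peak and 0 in WT (n = 3, limma adjusted p = 1.52e-05, centred). The B3-domain gene ABS2 had 3484 ± 239 bp, RPP13, an immune receptor, 2873 ± 518 bp, CIPK1, a kinase, 2814 ± 1097 bp, and ERD5, a proline dehydrogenase, 2661 ± 252 bp, all at 0 in WT. DIN10, a dark-inducible gene, rose from 26.0 ± 45.0 to 3990 ± 123.5 bp, BGAL1, a galactosidase, from 83.7 ± 145 to 4766 ± 178 bp, and PEN3, an ABC transporter, from 210.3 ± 364.3 to 5914 ± 39.0 bp. In these genes all but 1 of the WT libraries were at 0, and log2 values would rest on the 100 bp added. Over all genes tested the median log2 value of jaw-5D against WT was 2.68, 1.97 and 0.737 with 50, 100 and 500 bp added. Peaks of 2893 ± 899 bp at CA2, a carbonic anhydrase, and 2580.3 ± 122.9 bp at MYB30 were absent in WT. CPK32, WRKY33 and ATMS1 were among the 10 longest genes bound in all 3 jaw-5D libraries and 0 of WT, with 2551 ± 312, 2511 ± 101 and 2466 ± 232 bp.

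In pifQ, CA2 (chromosome 5, 4757972 to 4762615) had 3853 ± 128 bp and 0 in WT (centred adjusted p = 1.31e-05). GGT1, an aminotransferase of photorespiration, had 3320 ± 122.2 bp, GAPC2, a glycolytic enzyme, 3302 ± 175 bp, the trihelix gene GTL1 3001 ± 480 bp, and SFP1, a sugar transporter, 2790.3 ± 474.1 bp, all at 0 in WT. RPP13 had 2877 ± 190 bp and EXPA1, an expansin, 2660 ± 8.7 bp, and ATMS1, a methionine synthase, rose from 26.0 ± 22.5 to 3387 ± 284 bp. In hy5, CA2 had 3415 ± 502.5 bp, GGT1 3253 ± 170.3 bp, GAPC2 3139 ± 384 bp and EXPA1 2598 ± 103 bp, against 0 in WT. RCA, the Rubisco activase, rose from 36.0 ± 62.4 to 3034 ± 14.5 bp, and TBL45 reached 2272 ± 446 bp from 0. BGAL1 in pifQ (5181 ± 484 bp), DIN10 in both (3590.3 ± 97.8 and 3020 ± 168.5 bp), and MYB30, GTL1 and SFP1 in hy5 completed the largest changes. Centred adjusted p-values of these largest changes were between 1.31e-05 and 0.000376.

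Gibberellin genes were longer in every mutant, 9 of 9 tested without centring, 9 of 9 adjusted over the list alone, and 6, 7 and 7 with centring in jaw-5D, pifQ and hy5. Of all 11782 genes tested, 67.8, 68.6 and 61.7% were longer without centring, and 4151, 3906 and 3868 genes with it. All list counts against WT are to be read beside these values. The format of the lists coincides with the genotype here, so these changes cannot be assigned to genotype. RGA1, a DELLA repressor (chromosome 2, 255249 to 257550), rose from 89.0 ± 154 bp to 1965 ± 238, 2238 ± 78.5 and 1942 ± 272 bp (limma centred adjusted p = 0.000326, 0.000274 and 0.000337, n = 3). GAI, another DELLA gene, rose from 97.3 ± 84.4 to 847 ± 267, 2186 ± 296 and 1392 ± 528 bp, and RGL2 and GASA4 were at 0 in WT. The gibberellin list did not pass against other genes (camera adjusted p = 0.321, 0.126 and 0.220). Of 10 clock genes, 4, 3 and 5 were longer with centring, and 10, 9 and 9 adjusted over the list alone without it. ELF4 went from 0 to 625 ± 58.8, 579 ± 292 and 470 ± 72.5 bp. Of 14 elongation genes 6, 6 and 7 were longer with centring, DWF4, a brassinosteroid enzyme, and EXPA1 among them in each. Counts of longer genes adjusted over the list alone were 12, 11 and 12.

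Of 16 light genes 6, 8 and 7 were longer with centring, among them F3H, PSY and HY5 in each mutant. Adjusted over the list alone, without centring, 13, 13 and 11 were longer. HY5 went from 0 in WT to 322 ± 10, 306 ± 26.3 and 612 ± 109 bp. Of 16 TCP-linked genes 2, 5 and 2 were longer with centring, CYCD3;1 and GRF3 in each, and 10, 15 and 10 adjusted over the list alone. Of 4 PIF factors 1, 2 and 2 were longer with centring, PIL6 (PIF5) in each, and 4, 3 and 4 adjusted over the list alone. PIF3 was at 0 bp in all 3 pifQ libraries and in all but 1 of the WT libraries (72.3 ± 125 bp). For 8 housekeeping genes, 3 were longer in each mutant with centring (ACT2, ACT8 and GAPC1), while 4 were longer adjusted over the list alone. UBQ10 had 2367 ± 447 bp in WT and 2346 ± 47.2, 2453 ± 17.1 and 2562 ± 84.6 bp in the mutants. With centring, UBQ10 in each mutant, PIF3 in pifQ, and SAUR63 and CAB3 in jaw-5D passed as shorter. These calls come from the shift subtracted, are absent without centring and adjusted over the list alone, and are not taken as losses of PKL. Of 11 floral genes 1 passed with centring in each, AGL20, with 6, 7 and 6 adjusted over the list alone. LDL2 and PKDM7D, 2 of 3 demethylases tested, passed in each mutant, with 3 adjusted over the list alone. AGL15, 1 of 3 seed and embryo genes, passed in jaw-5D and hy5, and SCR, the 1 root gene tested, in pifQ and hy5. Adjusted over the list alone, 2 seed and embryo genes and 1 root gene were longer in each. In methyltransferases, remodelers and PRC2, with 3, 3 and 1 tested members, 0 passed with centring. Adjusted over the list alone, methyltransferases had 0, 1 and 0 longer, remodelers 2, 0 and 2, and PRC2 1, 0 and 0. The smallest camera adjusted p of any list against WT was 0.126.

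**Figure D3:**
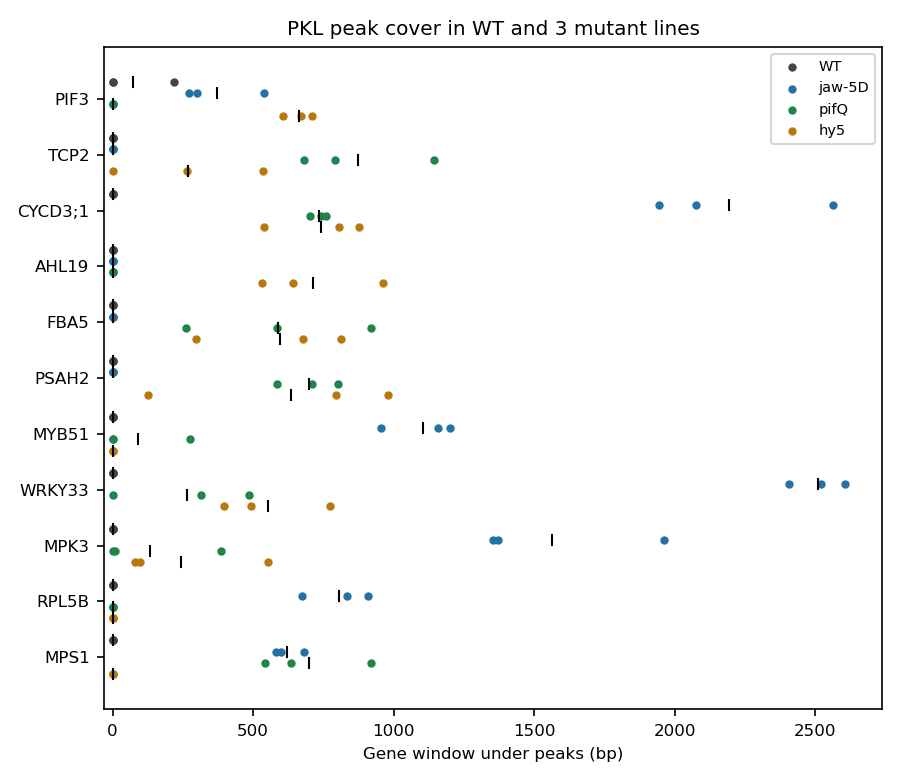
PKL peaks over named genes in WT, jaw-5D, pifQ and hy5, in bp under peaks over the gene and 1000 bp upstream, with 3 libraries per group (points) and their mean (tick). The genes shown were chosen from the named ones after their values were seen. CYCD3;1 has 2194 bp in jaw-5D, 734 in pifQ and 740.0 in hy5, and PIF3 has 0 bp in pifQ.

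Of 11782 genes tested, 4151 were longer and 169 shorter in jaw-5D than in WT after centring by -1.15. In pifQ, centring by -1.23 gave 3906 and 179, and in hy5, centring by -1.11 gave 3868 and 231. Without centring 7990, 8087 and 7264 were longer and 3, 2 and 3 shorter, and of the longer ones 5816, 5858 and 5119 were at 0 bp in every WT library. Unadjusted p-values were under 0.05 in 8377, 8473 and 7633 genes. Groups did not overlap in 7762, 7852 and 6831 genes with higher mutant values and in 2, 2 and 3 with lower ones, where chance gives 10%. Of 444 tRNA genes tested, 376, 392 and 360 were longer without centring. Peaks per library averaged 12731 ± 363 in jaw-5D, 13071 ± 805 in pifQ, 11701 ± 424 in hy5 and 1426 ± 1215 in WT (exact permutation p = 0.1 for each, n = 3). They covered 7.0 ± 0.185, 7.20 ± 0.342, 6.40 ± 0.428 and 0.518 ± 0.494 Mb. With q of at most 0.01 in every list, the ratios to WT were 8.68, 8.90 and 7.91, against 8.93, 9.17 and 8.21 before. The mean of WT rests on its replicate 3: without that library the ratios before matching were 17.52, 17.99 and 16.11, and without replicate 2 they were 6.99, 7.17 and 6.42. Genes bound in all 3 libraries of a mutant and 0 of WT numbered 5476, 5510 and 4613, and 2, 2 and 3 the other way. With equal numbers of peaks in every list, 214, 217 and 147 genes passed in all.

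The mutants were also compared with one another, where all lists have the same format. In pifQ against jaw-5D, TCP2 (chromosome 4, 10162953 to 10165562), a target of the microRNA raised in jaw-5D, had 872 ± 241 bp of PKL peak in pifQ and 0 in jaw-5D and in WT (n = 3, limma adjusted p = 0.00879). G3Pp1, a glycerol-3-phosphate permease, had 2329 ± 616 against 38.7 ± 67.0 bp (adjusted p = 0.0217), RGF9, a root growth peptide, 1165 ± 93.6 against 91.3 ± 158 bp, and CER1, of wax synthesis, 924 ± 176 against 80.7 ± 140 bp. PSAH2, of photosystem I, had 698 ± 109 bp against 0, the adjacent genes TSM1 and PIS1 548 ± 91.1 and 547 ± 102 bp, FBA5 588 ± 328.5 bp, ATK1, a kinesin, 483 ± 45.8 bp, and ENP 493 ± 180 bp. WRKY33, a transcription factor of defence (chromosome 2, 16108361 to 16110766), had 2511 ± 101 bp there against 266 ± 246 in pifQ (log2 -3.17, adjusted p = 0.0106), and the kinase gene MPK3 1562 ± 346 against 132 ± 221 bp (log2 -3.24). CNI1, a ubiquitin ligase, had 1289 ± 159 against 78.0 ± 135 bp, and MYB51, of indole glucosinolate synthesis, 1105 ± 132 against 91.3 ± 158 bp. RPL5B, a ribosomal protein gene, had 806 ± 120.0 bp in jaw-5D and 0 in pifQ. SIP2, SSN2 and RAD9 were shorter in pifQ as well, and UNE2 and OPR2 were at 0 there.

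In hy5 against jaw-5D, AHL19, an AT-hook gene (chromosome 3, 1230986 to 1232328), had 712 ± 224 bp in hy5 and 0 in jaw-5D (limma adjusted p = 4.85e-05, n = 3). FBA5 (596 ± 267 bp), bZIP16 (522 ± 25.2 bp), BEL10 (528 ± 144 bp), PSAH2 (633 ± 449 bp), ENP (391 ± 99.6 bp), TPPE (384 ± 94.0 bp) and TBL16 (371 ± 97.2 bp) were at 0 in jaw-5D too. FRO4 and CER1 were longer in hy5 (log2 2.59 and 2.23). MYB51 (1105 ± 132 bp in jaw-5D), SIP2, a raffinose-hydrolysing enzyme (1082 ± 542 bp), SSN2 (841 ± 258 bp), EDA40 (822 ± 162 bp), RPL5B, NRPD7 (831 ± 444 bp) and NAKR2 (641 ± 5.1 bp) were at 0 in hy5. CRK10, BCB, a blue copper protein, and RAN2, a small GTPase, were shorter in hy5 (log2 -3.20, -3.11 and -2.97). In hy5 against pifQ, AHL19 was at 0 in pifQ (centred adjusted p = 0.000443), as were UNE2 (603 ± 353 bp in hy5), NIMIN1 (487 ± 59.0 bp), LPAT2 (485 ± 31.6 bp), TBL16, ILL3 (372 ± 138 bp) and PMI2 (342 ± 89.8 bp). QSOX1 and XIH were longer in hy5 (centred log2 2.54 and 2.1). MPS1 (698 ± 197 bp in pifQ), MOD1, of fatty acid synthesis (694 ± 221 bp), PAP26, a phosphatase (625 ± 291 bp), SDR1 (527 ± 65.4 bp), JAL34 (553 ± 260 bp) and TAPX, a plastid peroxidase (478 ± 207 bp), were at 0 in hy5. So were PSRP3/1 (408 ± 82.5 bp in pifQ), EMB2770 (436 ± 263 bp) and QQS, a regulator of starch (411 ± 196 bp), and RABE1b was shorter in hy5 (centred log2 -2.66).

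Of the 14 lists, the PIF and TCP-linked ones alone had members that passed between mutants. PIF3 (chromosome 1, 3076582 to 3079539) had 370.3 ± 146.7 bp in jaw-5D, 0 in pifQ and 662 ± 52.3 bp in hy5 (limma adjusted p = 0.0224 for pifQ against jaw-5D, and 0.00159, centred, for hy5 against pifQ). CYCD3;1, a D-type cyclin (chromosome 4, 16357639 to 16359555), fell from 2194 ± 326 bp in jaw-5D to 734 ± 30.1 in pifQ (log2 -1.45, adjusted p = 0.00384) and 740.0 ± 178.4 in hy5 (log2 -1.46, adjusted p = 0.00351). Adjusted over the list alone, pifQ against jaw-5D had 1 PIF factor longer and 1 shorter, and 2 TCP-linked genes longer and 1 shorter. For hy5 against jaw-5D these counts were 0 and 0, and 1 and 2, with 1 light gene longer and 2 shorter, and 1 elongation, 1 floral and 1 PRC2 gene shorter. For hy5 against pifQ, 1 PIF factor was longer and 1 shorter, 1 light gene longer, and 1 elongation and 1 floral gene shorter. The smallest camera adjusted p of a list between mutants was 0.423.

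Of the 11782 genes, 159 were longer and 131 shorter in pifQ than in jaw-5D, and 1574 had an unadjusted p under 0.05. The counts turned to 123 and 131 with centring, to 121 and 143 without pifQ replicate 1, and to 108 and 142 without pifQ replicate 3, so neither direction prevails. In hy5 against jaw-5D 76 were longer and 224 shorter, with 1734 at an unadjusted p under 0.05. With equal numbers of peaks in every list, which left 931 genes to test, 25 were longer and 33 shorter. In hy5 against pifQ 22 were longer and 102 shorter after centring by 0.11, and 22 and 126 before. Of these genes 1421 had an unadjusted p under 0.05, and equal numbers of peaks gave 7 longer and 10 shorter. Leaving out hy5 replicates 1, 2 and 3 in turn raised the total of the last comparison, without centring, from 148 to 224, 229 and 253. Its 22 longer genes became 50, 39 and 52 without pifQ replicates 1, 2 and 3, and 37, 38 and 32 without hy5 replicates 1, 2 and 3. Groups did not overlap in 1110 and 967, in 576 and 1424, and in 412 and 1339 genes, 17.6%, 16.98% and 14.9% against a chance share of 10%.

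RNA-seq of pkl gave the expression level of marked genes. Median FPKM of genes with H3K4me1, H3K4me2 or H3K4me3 in all 3 pkl libraries was 15.9, 12.5 and 17.1, and that of genes with the mark in no pkl library was 0. Across genes, which are not independent replicates, FPKM and bp under peaks in pkl had Spearman correlations of 0.566 for H3K4me1, 0.638 for H3K4me2 and 0.799 for H3K4me3. Genes marked in pkl and not in WT had median FPKM of 1.76, 4.06 and 4.17, and those marked in WT and not in pkl 9.61, 1.09 and 2.42. PKL transcripts were still counted in pkl, 1697, 1789 and 1940 reads (29.6, 31.9 and 33.9 FPKM). The labels name no pkl allele, so what PKL activity remains is unknown. Of the genes whose H3K4me1 peak was absent in pkl, FBA1, HOG1 and PFN2 had 1354, 727 and 649 FPKM in pkl.

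**Figure D4:**
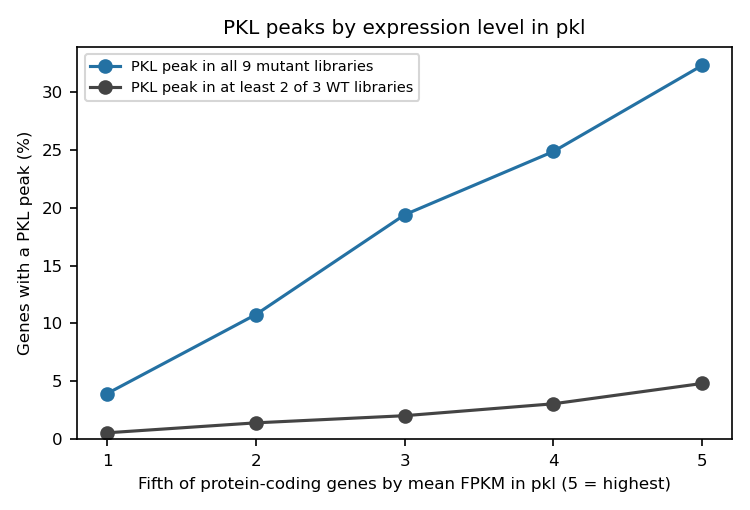
Percent of protein-coding genes with a PKL peak (vertical axis) for 5 equal bins of these genes ranked by expression in pkl (FPKM, horizontal axis, lowest to highest). The lines are genes with a peak in all 9 mutant libraries, from 3.93 to 32.3%, and in at least 2 of 3 WT libraries, from 0.543 to 4.81%.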

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

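The comparisons between mutants, the test of q thresholds, those of depth of the WT libraries, of PKL binding of more genes and of a library-wide shift in peak length, and all counts over other splits of the libraries were chosen only after the results were seen.

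PKL peak length differed between mutants at 290 genes for pifQ against jaw-5D, at 300 genes for hy5 against jaw-5D and at 148 genes for hy5 against pifQ (limma, 3 libraries per group, without centring; 124 genes for hy5 against pifQ with it). These differences were tested directly in the fit of all 12 PKL libraries. Replicate 3 of the PKL lists of WT held 3 chloroplast peaks, a signal outside the nuclear genes compared, and all other lists held 0 chloroplast and mitochondrial peaks.

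With 3 libraries against 3 there are 10 splits, so the share of splits with as many called genes cannot fall under 0.05; in each of the 9 comparisons 1 split, the real one, reached the real count. Without centring, the real count and the highest of the other splits were 94 and 54 for H3K4me1, 331 and 48 for H3K4me2 and 251 and 24 for H3K4me3. Against WT they were 7993 and 0 for jaw-5D, 8089 and 0 for pifQ, and 7267 and 0 for hy5. Between mutants they were 290 and 71 for pifQ against jaw-5D, 300 and 63 for hy5 against jaw-5D, and 148 and 68 for hy5 against pifQ. For genes marked in 1 group alone, the real count and the highest other split were 92 and 68 for H3K4me1, 247 and 62 for H3K4me2, and 168 and 27 for H3K4me3. For jaw-5D, pifQ and hy5 against WT these were 5478 and 25, 5512 and 17, and 4616 and 27. In both counts against WT, every other split mixes WT and mutant lists in each group. The large difference in peak numbers then lies inside both groups, which by itself holds the count at or near 0. Any cause of that difference, genotype or processing, would give the same low counts.

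The mutant lists held many more PKL peaks than the WT lists, with means from 11701 to 13071 against 1426. Different q thresholds were argued against as the whole cause, since with q of at most 0.01 in every list the lowest ratio was still 7.91. A lower depth of the WT libraries is a candidate explanation that met its test. Among peaks with -log10 p between 5 and 6, a range above the lowest p of every list, the lowest WT median fold enrichment was 3.34 and the highest mutant one 2.24, a gap of 1.0992, as in libraries where fewer reads need a larger fold to reach the same p. This p, unlike q, does not depend on the number of peaks in a list. A different control or scaling of the WT libraries could raise the fold too and was not tested. PKL binding of more genes in the 3 mutants stays open and cannot be told apart from the processing of the lists, because 0 of the WT lists and all mutant lists hold peaks with -log10 q under 2.

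More genes had longer than shorter H3K4 methylation peaks in pkl. A library-wide shift in peak length was argued against as the whole cause for H3K4me3 alone, where after centring 69.6% of called genes were still longer, and at least 64.0% with any 1 library left out (lower 95% binomial limit 57.4%). The binomial limits cover counting error only, because called genes come from the same libraries and are not independent. The library-wide shift stays open for H3K4me1, with 77.5% longer after centring but 55.2% without pkl replicate 3 (lower limit 45.7%). It also stays open for H3K4me2, with 59.5% and 42.9% without pkl replicate 2. Centring does not correct for peaks that are found or missed, and 63, 135 and 105 of the longer genes of H3K4me1, H3K4me2 and H3K4me3 (without centring) were at 0 bp in every WT library. A higher depth or enrichment of the pkl libraries stays open, as every pkl list had a lower median fold at like q than every WT list in 2 of 3 marks and the ranges overlapped in the other. Loss of PKL from its bound genes could not be settled, and the labels name no pkl allele: the highest odds ratio of a WT PKL peak among longer genes was 0.935 with an adjusted p of 1 by Fisher's exact test, which met the condition set beforehand against it; with centred calls the highest was 1.18, also with an adjusted p of 1. It is left open because the 95% intervals reach 2.44, 2.08 and 1.83 for H3K4me1, H3K4me2 and H3K4me3 with few bound genes, a criterion added after the ratios were seen. When bound meant at least 1 WT library, which gave more bound genes, the odds ratios among longer genes were 0.528, 0.898 and 0.928. Their 95% intervals reached 1.61, 1.43 and 1.48.

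PKL peaks lay over highly expressed genes, and in the mutants over tRNA genes. Protein-coding genes were put into 5 equal bins from lowest to highest expression in pkl. The share with a peak in all 9 mutant libraries was 3.93, 10.8, 19.4, 24.9 and 32.3% over these bins. Of tRNA genes 49.3% had such a peak, against 18.3% of all protein-coding genes. General enrichment of highly transcribed DNA in the ChIP may account for this, and its test, the share in the top bin over that in the bottom bin, gave 8.22. PKL binding of transcribed genes would give the same gradient and was not tested separately, because no anti-PKL ChIP of pkl was analysed here. In the WT lists the share of protein-coding genes with a peak in at least 2 of 3 libraries rose as well, from 0.543 to 4.81% over the 5 bins. Among all tRNA and all protein-coding genes it was 2.41 and 2.37%.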

How the results depend on the processing

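Added after the data were seen were the matched q threshold of 0.01, its combination with centring, centred calls among PKL-bound genes, centred counts with 1 library left out, and the comparisons between mutants, for which peaks per library and genes marked in 1 group alone are not reported. Of 408 alternatives to 48 results, 341 stayed within the limits set, 56 moved a value, 6 lost the threshold and 5 turned a direction. For peaks per library and the genome covered, the limit was an unchanged sign only. A replicate block leaves those differences the same by construction, so its place among the 341 shows nothing. Counts of genes were compared by their totals, within 1.5 times. The majority direction of such a count turned in 8 alternatives, 7 of them within that limit: longer and shorter H3K4me2 to 156 and 178 without pkl replicate 2 (145 and 193 centred), pifQ against jaw-5D to 123 and 131 with centring, 127 and 142 with centring and the matched q threshold, 121 and 143 without pifQ replicate 1 and 108 and 142 without pifQ replicate 3, and H3K4me2 in pkl or WT alone to 125 and 134 with equal numbers of peaks and 190 and 197 without pkl replicate 2. For results that moved, the cause was not tested unless named. Directions turned in H3K4me1 peaks per library, -219 at first, which were 1899 with stricter peaks (-log10 q of at least 10) and 10.3 without pkl replicate 1 (range over libraries left out -513 to 10.3), and in PKL-bound genes among shorter H3K4me2, where the odds ratio was 0.917 with genes bound in at least 1 WT library. With centred calls the odds ratio turned to 1.18 among longer H3K4me2 and to 1.16 among shorter H3K4me3. Called genes with stricter peaks were 332 for H3K4me1 and 2588, 2810 and 2194 for jaw-5D, pifQ and hy5 against WT. Equal numbers of peaks gave 214, 217 and 147 for these mutants, and 84, 58 and 17 for pifQ against jaw-5D, hy5 against jaw-5D and hy5 against pifQ. That setting removes most mutant peaks by construction. Centring gave 4320, 4085 and 4099 for jaw-5D, pifQ and hy5 against WT, and together with the matched q threshold 4094, 3869 and 3863. Non-overlap in place of the test, where chance gives 10% of genes, gave 1896, 4317 and 3329 for H3K4me1, H3K4me2 and H3K4me3, and 2077, 2000 and 1751 between mutants. Genes marked in 1 group alone numbered 326 for H3K4me1, 473 for H3K4me2 and 2039, 2259 and 1599 for jaw-5D, pifQ and hy5 against WT with stricter peaks. They numbered 123, 107 and 76 with equal numbers of peaks, 2466, 2502 and 2109 with an overlap of 500 bp, and 403 for H3K4me2 with merged regions. List calls were lost with an estimated correlation, with adjusted p = 0.545 for housekeeping genes in H3K4me1, 0.237 for floral and 0.682 for PRC2 genes in H3K4me2 and 0.579 for elongation genes in H3K4me3. The fry test does not compare a list with other genes and so asks another question. It gave adjusted p = 0.0578 for the housekeeping and 0.149 for the elongation list. CPM, which unlike FPKM is not divided by gene length, gave Spearman correlations of 0.637, 0.689 and 0.822 across genes. Bp under peaks can grow with gene length as well, so these values are not corrected for it.

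With 1 library left out at a time and the genes of the full test kept, a choice made after a filter applied again had emptied 1 direction by construction, called genes without centring ranged from 80 to 122 for H3K4me1, 264 to 400 for H3K4me2 and 208 to 330 for H3K4me3. They ranged from 7161 to 8008, 7212 to 8145 and 6152 to 7056 for the mutants against WT, and from 239 to 270, 267 to 352 and 177 to 253 between mutants. Centred counts ranged from 271 to 338 for H3K4me2, 3305 to 4428, 3063 to 4290 and 3261 to 4390 for the mutants against WT, and 145 to 211 for hy5 against pifQ, from 124. Genes marked in 1 group alone ranged from 173 to 191, 363 to 400 and 205 to 240 for the marks and from 5520 to 6870, 5554 to 6935 and 4657 to 5994 for the mutants, since fewer libraries have to share a peak. A replicate block gave 0 called genes for H3K4me1, 159 for H3K4me2 and 187 for pifQ against jaw-5D. Deviations from the group mean correlated by -0.088 to 0.0812 across genes between replicates of the same number. Replicates were therefore not treated as pairs. Logistic regression with gene length could not be fitted for H3K4me1, where 0 changed genes were bound.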

Other observations

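Genes with gained peaks were set beside their expression in pkl. Genes called longer, without centring, had median FPKM of 2.18 in H3K4me1, 9.50 in H3K4me2 and 5.66 in H3K4me3, against 14.9, 12.5 and 16.5 for all genes tested. Genes called shorter had medians of 10.3, 1.75 and 2.68. Of the longer genes, 63 of 74, 135 of 222 and 105 of 186 were at 0 bp in every WT library. Lower medians than among all genes tested can follow from that selection alone. AGL99, which gained an H3K4me1 peak, was listed at 0 FPKM, and DFO and SYTB stood at 0.106 and 0.125. FRO3 and UBC5, with gained H3K4me1 peaks as well, had 53.6 and 47.5 FPKM, and SQE6, with a gained H3K4me3 peak, had 142. WUS and COPT3, which lost H3K4me2 peaks, were listed at 0, and JAG and SHP2 had 0.295 and 0.385 FPKM. These levels are from pkl alone, and whether they differ from WT was not tested.

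At some loci of the mutated or microRNA-targeted factors, PKL peaks were present in the mutant itself. PIL5 (PIF1) had 1285 ± 98.1 bp in pifQ and 366 ± 14.2 bp in jaw-5D, and HY5 had 612 ± 109 bp in hy5 and 322 ± 10 bp in jaw-5D (mean ± SD, n = 3). Against jaw-5D, both passed adjusted over their list alone and neither over all genes. Against WT, HY5 passed over all genes with centring, as given above. In pifQ, PIF4 and PIF5 had 1076 and 2137 bp and PIF3 had 0. In jaw-5D, of the TCP genes targeted by the microRNA, TCP10, TCP3, TCP4 and TCP24 had 1033, 285, 212 and 48.7 bp on average, and TCP2 had 0, as in WT. TCP4 was at 0 bp in jaw-5D replicate 3, and TCP24 had a peak in replicate 2 alone (146 bp). Means of TCP10, TCP3, TCP4 and TCP24 were 1312, 470, 184 and 138 bp in pifQ, and 953, 309, 190 and 0 bp in hy5. Of the 718 genes with a PKL peak in at least 2 WT libraries, 702 also had one in all 9 mutant libraries.

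As a hypothesis, the missing PKL peak over PIF3 in pifQ may reflect absence of that stretch of DNA from the pifQ genome. The 0 bp in pifQ had been seen before the flanking genes were examined. The nearest genes with PKL peaks on either side, AT1G09520 at 4532 bp and AT1G09550 at 10194 bp, carried peaks in 3 of 3 pifQ libraries, with 742 ± 148 and 85.3 ± 15.0 bp, so that a deletion would have to lie between them. A loss of PKL from an intact PIF3 gene would look alike in peak lists and was not tested.

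A second hypothesis was that genes with longer peaks in pkl lie near one another along the chromosomes. Pairs of such genes 5 to 50 kb apart numbered 4 in H3K4me1 (mean of 10000 random draws 2.65, permutation p = 0.274), 24 in H3K4me2 (22.6, permutation p = 0.411) and 11 in H3K4me3 (15.9, permutation p = 0.918). Adjusted over the 3 tests, p was 0.616, 0.616 and 0.918. No excess was found at this distance.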
